A study of Mus musculus with 22 samples.

How the data were processed

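Liver RNA of male C57BL/6J mice was measured by polyA-selected, strand-specific RNA sequencing in 22 libraries, in 2 cohorts of 11. The cohorts differ in the disease model and each carries its own normal-diet group: one was fed a high-fat diet (HFD, labelled as the fatty liver disease model) and one a methionine- and choline-deficient diet (MCD, labelled as the steatohepatitis model). Each cohort has 3 groups: normal diet with vehicle, disease diet with vehicle, and disease diet with DTMB, a compound known here only by this code name and given by mouth at 10 mg/kg per day. Replicates are numbered as biological replicates in the labels.

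The deposited tables hold raw read counts per gene, whole numbers with no normalization. Per the submitters' processing notes, FastQC 0.11.7, Trimmomatic 0.38, HISAT2 2.1.0, StringTie 2.1.3b and the mm10 build were used; which step each tool served in, and the settings, are not given in the sources used here. The deposited counts list 45777 genes, of which 20101 had no count in any library. Totals ran from 50.1 to 66.7 M counts per library. How counting treated reads shared between near-identical genes is not stated, so values of the Mup, Cyp2a, Cyp2b, Cyp4a, Sult2a, Serpina1 and Ifit3 families may be split between copies and are uncertain for single members. Gene positions are from the GRCm38.p6 (mm10) RefSeq table, which matched 45679 of the 45777 gene IDs.

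Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr on the group design, TMM factors, estimateDisp, and the quasi-likelihood F test of glmQLFit and glmQLFTest at their defaults. Each cohort was fitted alone with its 3 groups, and both cohorts together for the differences between cohorts. P-values were adjusted by Benjamini-Hochberg over all genes tested and called at 0.05 with no fold cutoff. Log2 fold changes are given with their standard error (SE), computed from the coefficient and its F statistic. CPM values are counts over the TMM-scaled library size, computed here within each cohort, so levels of the cohorts are not on one scale. The summed acinar list, Xist and the Y-linked genes are the exception, given over the total counts of the library without TMM factors. A fold against a group with no count was set against a floor of 3 counts over the group and covers counting error only. DTMB was tested against the vehicle group on the same diet, and the diet against normal diet within the cohort. Both comparisons of a cohort share the disease-diet vehicle libraries, so 20 sets of counts with no group difference were simulated per cohort, and the vehicle libraries were also split into 2 sets of 2, 1 set for each comparison. In the simulated sets each gene was drawn independently, so they lack the correlation between genes of the real libraries.

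Before the data were examined, 41 gene lists with 995 entries were fixed for pathways, liver cell types, other tissues and RNA quality. They were tested with camera at a preset correlation of 0.01 (limma 3.58.1), with a correlation estimated for each list, and with fry. Genes were named by a rule fixed at the same time: per comparison the 3 largest rises and 3 largest falls among called genes whose libraries did not overlap (mean CPM of at least 1 in the higher group, no predicted or clone names), the 3 members of smallest p in each of the 6 lists of smallest camera p, the 2 of smallest p in each list of a study theme, and the member of smallest p in every other list described. Reversal and differences between cohorts took the 6 genes of smallest p. Which of the other lists are described was decided after their results were seen.

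Fixed with the lists were these other settings: DESeq2 1.42.0, limma-voom with sample quality weights, RLE factors, no count filter, a stricter filter (CPM above 1 in 3 libraries), only the groups compared, all libraries in one fit, an absolute log2 fold change of at least 1, a replicate block, and leaving out each library. Scaling by library size alone, and leaving out libraries whose summed pancreatic acinar list was above 100 CPM, were added after seeing the data. Libraries of the same replicate number did not show as pairs in their deviations from the group mean. Their correlations were -0.444 to 0.3395 in the HFD cohort and -0.269 to 0.0826 in the MCD cohort. They were treated as unpaired, but this check does not exclude a pairing. No pair of libraries of a group agreed within sampling noise (lowest chi-square per degree of freedom 26.1).

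The procedure was tested on simulated counts with 200 changed genes in each comparison. Of genes changed 2-fold it recovered 68.7% in the HFD diet comparison, among 15359 genes fitted, and 77.3% in the HFD DTMB comparison, among 15367. For the MCD diet comparison the share was 52.3% with 15673 genes fitted. For the MCD DTMB comparison it was 42.4% with 15710 genes fitted, and 6.06% of genes changed 1.5-fold. Figures were drawn with matplotlib 3.10.9.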

Results

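The count tables cover 22 liver libraries. The HFD cohort has 3 normal-diet, 4 HFD vehicle and 4 HFD DTMB libraries, with mean totals of 58.4 ± 5.28, 60.0 ± 1.60 and 58.8 ± 4.97 M counts (SD). The MCD cohort has 4 normal-diet, 4 MCD vehicle and 3 MCD DTMB libraries, with 59.0 ± 2.81, 63.7 ± 2.05 and 56.7 ± 7.04 M counts. Libraries of a group correlated at 0.966 to 0.986 in log2 CPM across genes, which are not independent replicates. Pancreatic acinar transcripts (digestive enzymes such as Amy2a5, Try5 and Ctrb1) were present in some libraries. Their summed list reached 1452 and 1295 CPM in normal-diet replicates 1 and 3 of the HFD cohort, 487 and 3409 CPM in HFD vehicle replicates 1 and 4, 1794 CPM in HFD DTMB replicate 3 and 374 CPM in normal-diet replicate 4 of the MCD cohort. The highest value in any other library was 12.9 CPM.

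**Figure D1:**
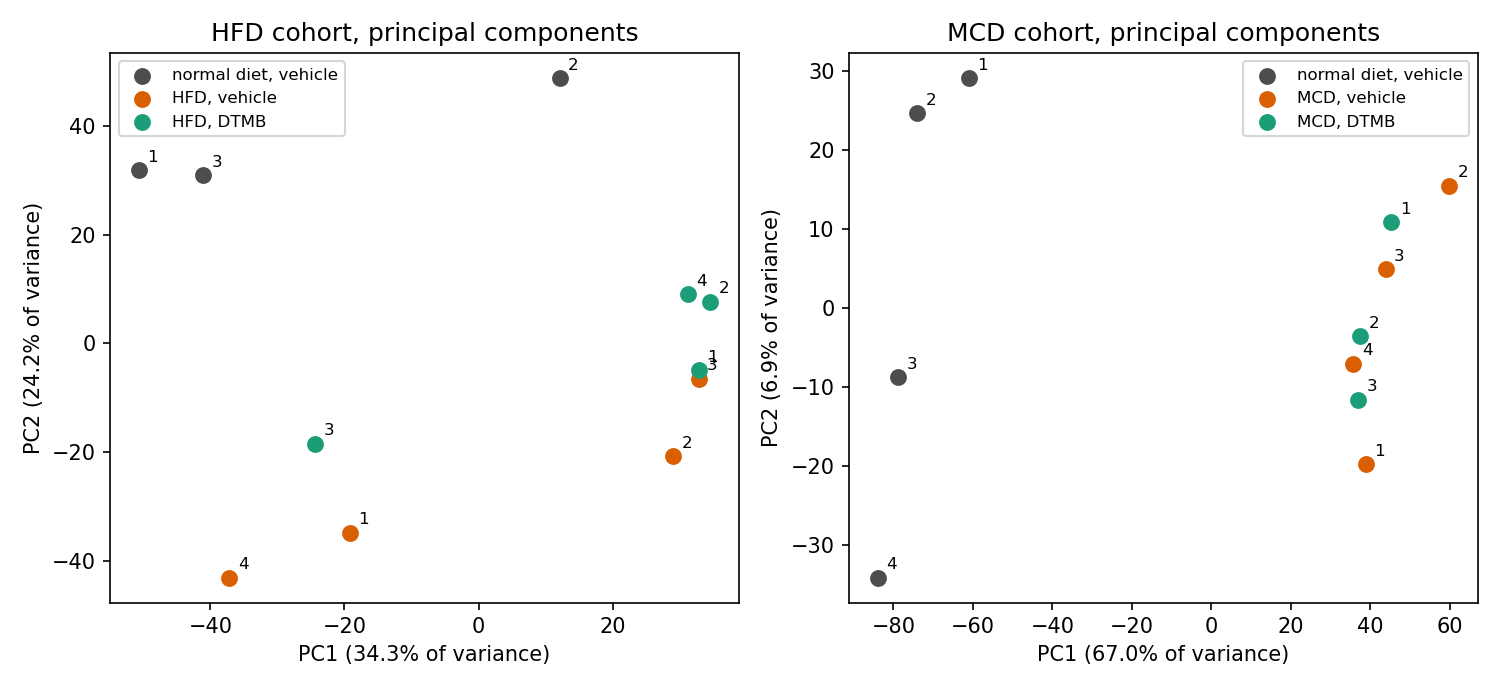
Principal components of log2 CPM of the 2000 most variable genes in the HFD cohort (left) and the MCD cohort (right); each point is a library, numbered by replicate, with the share of variance on each axis. In the MCD cohort PC1 (66.95% of variance) separates the normal-diet libraries from both MCD groups; in the HFD cohort PC1 (34.3%) has the libraries with acinar transcripts at negative values and the others at positive values.

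**Figure D2:**
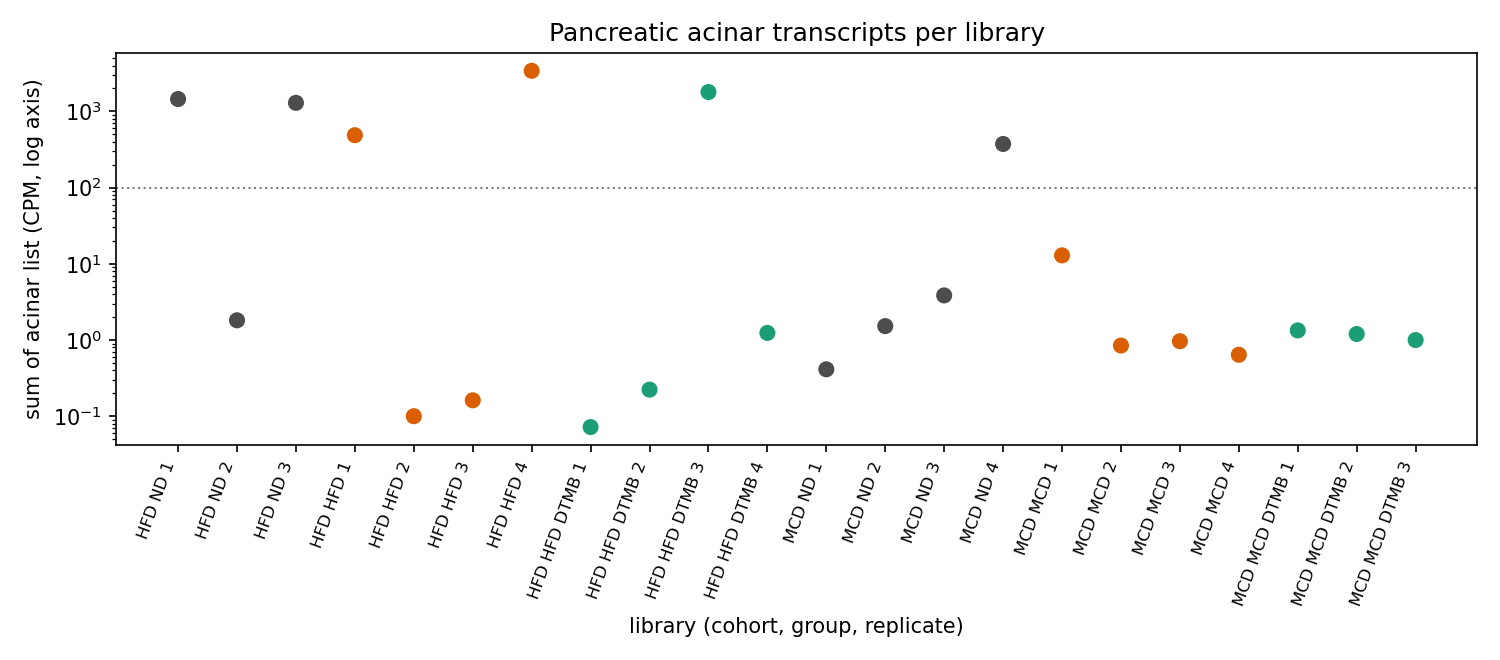
Summed CPM of the pancreatic acinar list (y axis, log scale) in each library (x axis), coloured by group; the dotted line is at 100 CPM. 5 libraries of the HFD cohort and 1 of the MCD cohort lie above it.

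The first comparison set HFD vehicle livers against normal-diet livers of the same cohort. On HFD, 29 of 34 interferon-stimulated, 16 of 19 antigen-presentation, 17 of 25 cholesterol-synthesis and 19 of 39 matrix genes (1 lower) were higher, and 20 of 46 fatty-acid oxidation genes (3 higher) were lower. The calls of these lists were lost with an estimated correlation (adjusted p = 0.637), while by fry they passed (adjusted p = 0.00562 to 0.0300). The largest rises were Cyp2b9 (gene ID 13094, chromosome 7, 26173350 to 26210661), a cytochrome P450 of female-typical expression, with 131 ± 109 CPM (SD, n = 4) against 0.157 ± 0.136 CPM (SD, n = 3) and a log2 fold change of 9.72 ± 0.93 (SE); Hao2 (gene ID 56185, chromosome 3, 98874519 to 98895376), 6.59 ± 1.03; and Sprr1a (gene ID 20753, chromosome 3, 92483954 to 92485881), 6.53 ± 1.23. The largest falls were Cpne5 (gene ID 240058, chromosome 17, 29156521 to 29237790), -4.14 ± 0.74; Lepr (gene ID 16847, chromosome 4, 101717137 to 101815352), the leptin receptor, -3.63 ± 0.25; and Asns (gene ID 27053, chromosome 6, 7675165 to 7693209), asparagine synthetase, -3.54 ± 0.33. Their adjusted p lay between 9.21e-06 and 0.00189 in edgeR's quasi-likelihood test.

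Of 34 interferon-stimulated genes, 29 were higher and 0 lower, among them Ifit3 (2.13 ± 0.20), Ifit3b (2.20 ± 0.22) and Ifit1 (1.85 ± 0.19). The list of MHC class II and other antigen-presentation genes had 16 of 19 members higher and 0 lower, with Psmb9 at 1.93 ± 0.20, the peptide transporter Tap1 at 1.16 ± 0.15 and Tapbp at 0.59 ± 0.079. Monocyte and lipid-associated macrophage markers had 15 of 23 higher and 1 lower. Ctsb rose by 0.49 ± 0.068 and Cx3cr1 by 2.74 ± 0.40, and Cd9 fell (-0.71 ± 0.099). Among Kupffer and pan-macrophage markers 8 of 18 were higher and 0 lower, with Mpeg1 at 1.59 ± 0.30. Of 25 chemokines and cytokines, 12 were higher and 0 lower, with the neutrophil chemokine Cxcl1 at 3.08 ± 0.40 and Cxcl10 at 2.71 ± 0.41; adjusted over the list alone, 13 were higher and 0 lower. The NF-kB and Toll-like receptor list had 10 of 30 higher and 1 lower, led by Tnfaip3 (1.18 ± 0.22). Among lists that track RNA quality and handling, immediate-early genes had 6 of 17 higher and 0 lower (Klf6 0.78 ± 0.17), and mitochondrially encoded genes 3 of 13 lower and 0 higher (ND5 -0.50 ± 0.086). Camera adjusted p ran from 1.92e-18 for the interferon list to 0.00412 for the NF-kB list, and was 0.0204 and 0.0254 for the last 2. Under an estimated correlation the adjusted p of these lists was 0.637 to 0.638, so none held. By fry all passed except the Kupffer and mitochondrially encoded lists (adjusted p = 0.0909 for both).

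Of 39 matrix genes, 19 were higher and 1 lower, with the fibrillar collagens Col3a1 (2.48 ± 0.33) and Col1a1 (2.57 ± 0.41) higher and Ccn2 lower (-1.04 ± 0.17); adjusted over the list alone, 23 were higher and 2 lower. Of 25 cholesterol-synthesis genes, 17 were higher and 0 lower, with Acat2 at 0.82 ± 0.085, Mvd at 2.24 ± 0.26 and Msmo1 at 2.103 ± 0.29; adjusted over the list alone, 19 were higher and 0 lower. Of 46 genes of fatty-acid oxidation and PPARalpha targets, 3 were higher and 20 lower. Ehhadh, an enzyme of peroxisomal beta-oxidation, fell to 644 ± 116 CPM (SD, n = 4) against 3948 ± 527 CPM (SD, n = 3), -2.62 ± 0.19 on the log2 scale, while Hadh rose by 0.66 ± 0.071; adjusted over the list alone, 3 were higher and 22 lower. Of 21 lipogenesis genes, 7 were higher and 3 lower (adjusted over the list alone, 9 were higher and 3 lower), with Pklr at 1.40 ± 0.17 and Acacb at -1.35 ± 0.19. Of 28 lipid droplet and uptake genes, 7 were higher and 3 lower (adjusted over the list alone, 7 were higher and 4 lower), with Fitm1 at 1.26 ± 0.16 and the lipase Pnpla2 at -0.85 ± 0.12. Proliferation genes had 20 of 37 higher and 1 lower, with E2f1 at 1.38 ± 0.15, Tpx2 at 2.15 ± 0.41 and Mki67 at 1.86 ± 0.37. Male-biased liver genes had 10 of 22 lower and 2 higher, with C8b at -1.22 ± 0.14. Camera adjusted p was 1.89e-08 for cholesterol synthesis, 4.12e-06 for matrix, 4.12e-06 for oxidation, 0.136 for lipogenesis and 0.383 for lipid droplet genes. The adjusted p with an estimated correlation of the lists named here was 0.637 to 0.662. The acinar list had no member past the threshold (Amy2a5 -1.03 ± 2.60, adjusted p = 0.800), with high values in both groups. The list of adipose, mesothelial and muscle genes had 4 of 14 lower and 1 higher (Car3 2.95 ± 0.29), with a median of -0.73 that turned to 1.80 without the acinar libraries (camera adjusted p = 0.672 with all, and 0.846 with an estimated correlation). The lower ones were the skeletal muscle genes Acta1, Ckm, Mylpf and Tnnt3, at 70.5, 38.9, 10.7 and 35.6 CPM in normal-diet replicate 1 and at most 0.712, 0.464, 0.650 and 0.294 CPM in the other libraries of the cohort.

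In all, 4332 of 15597 genes passed the threshold, 2374 higher and 1958 lower, of which 850 and 289 had an absolute log2 fold change of at least 1. Scaling by library size alone gave 3361 higher and 1030 lower, with the median of all genes at 0.14 on the log2 scale against 0.02, and the changes above are relative to the TMM scale; 2 of 19 lists past camera lost the call by library-size scaling, the immediate-early list among them (adjusted p = 0.0708 to 0.1096). Without the 5 libraries with acinar transcripts, which leaves 1 normal-diet library assumed to vary like the others, 655 genes passed; 21 of 72 subsets of the same group sizes, this one included, gave as few (median 906.5, highest 2131). The median absolute log2 fold change of the 4331 called genes tested in both was then 0.520 with a median SE of 0.174, against 0.566 and 0.119 with all libraries.

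The second comparison set HFD livers of mice given DTMB against HFD vehicle livers. With DTMB, 20 of 39 matrix genes, 10 of 30 NF-kB and Toll-like receptor genes, 6 of 25 chemokines and cytokines (1 higher) and 8 of 23 monocyte and lipid-associated macrophage markers were lower. Of 18 Kupffer and pan-macrophage markers 1 was, near the share over all genes (942 of 15597). 17 of 48 respiratory chain subunits, 12 of 21 secreted hepatocyte proteins and 10 of 22 male-biased genes were higher, and none of these lists held with an estimated correlation (adjusted p = 0.478 to 0.546). By fry the matrix, NF-kB, monocyte, respiratory chain and secreted lists passed (adjusted p = 0.0337 to 0.0405). The chemokine, male-biased and Kupffer lists did not (fry adjusted p = 0.0501, 0.0627 and 0.181). The largest rises were Hsd3b5 (gene ID 15496, chromosome 3, 98618636 to 98645534), a male-typical steroid dehydrogenase, with 70.8 ± 24.6 CPM (SD, n = 4) against 9.34 ± 8.93 CPM (SD, n = 4) and a log2 fold change of 2.92 ± 0.81; Scara5 (gene ID 71145, chromosome 14, 65666403 to 65764826), a ferritin receptor, 2.08 ± 0.53; and Tff3 (gene ID 21786, chromosome 17, 31125306 to 31129611), 2.03 ± 0.57. The largest falls were Sprr1a, -4.12 ± 0.83; Cidea (gene ID 12683, chromosome 18, 67343564 to 67367794), a lipid droplet protein, -3.14 ± 0.47; and Acod1 (gene ID 16365, chromosome 14, 103047012 to 103056573), the itaconate-forming enzyme of activated macrophages, -3.09 ± 0.87. Their adjusted p lay between 0.00779 and 0.0392.

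Of 39 matrix genes, 0 were higher and 20 lower; adjusted over the list alone, 0 were higher and 30 lower. Col1a1 was 4.04 ± 1.80 CPM (SD, n = 4) against 17.3 ± 6.25 CPM (SD, n = 4), a log2 fold change of -2.099 ± 0.36, with Col15a1 at -1.25 ± 0.20 and Col6a3 at -1.06 ± 0.18. Of 25 chemokines and cytokines, 1 was higher and 6 lower, with the monocyte chemokine Ccl2 at -2.58 ± 0.44 and Il1b at -1.91 ± 0.40; adjusted over the list alone, 1 was higher and 15 lower. The NF-kB and Toll-like receptor list had 10 of 30 members lower and 0 higher, with Tnfaip3 at -1.31 ± 0.20, Tlr5 at -0.68 ± 0.11 and Nfkbie at -1.08 ± 0.21. Antigen-presentation genes had 10 of 19 lower and 0 higher (Tapbp -0.36 ± 0.072, Tap1 -0.53 ± 0.14, Tap2 -0.50 ± 0.13), and interferon-stimulated genes 14 of 34 lower and 0 higher (Oasl2 -1.05 ± 0.23 and Gbp6 -1.39 ± 0.31). Monocyte and lipid-associated macrophage markers had 8 of 23 lower and 0 higher, with Cd9 at -0.44 ± 0.093, Ms4a7 at -2.08 ± 0.51 and Capg at -1.002 ± 0.24. Of 18 Kupffer and pan-macrophage markers 1 was lower, Cd14 (-1.45 ± 0.29). So was 1 of 16 stellate markers, Pdgfrb (-0.81 ± 0.20), and 1 of 17 endothelial markers, Lyve1 (-0.77 ± 0.23). These shares are near that of all genes tested (942 of 15597 lower). Immediate-early genes had 3 of 17 lower and 1 higher (Ier2 0.76 ± 0.14), and erythroid genes 2 of 9 higher and 0 lower (Hbb-bs 1.01 ± 0.29). Camera adjusted p was 2.78e-16 for matrix, 1.64e-06 for chemokines, 6.12e-08 for the monocyte list, 0.0443 for immediate-early and 0.0323 for erythroid genes. With an estimated correlation the adjusted p of the lists named here was 0.478 to 0.546. Acinar transcripts were present in 2 of the 4 vehicle libraries and 1 of the 4 DTMB libraries, and no member of that list passed the threshold (Try5 -1.36 ± 2.03, adjusted p = 0.687; without vehicle replicate 4 its log2 fold change was 1.07).

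Of 48 nuclear-encoded respiratory chain subunits, 17 were higher and 0 lower, with Uqcrq at 0.49 ± 0.087, Ndufb8 at 0.49 ± 0.093 and Ndufa2 at 0.44 ± 0.089. Secreted hepatocyte proteins had 12 of 21 higher and 0 lower, with Serpina1a at 0.38 ± 0.086, and male-biased genes 10 of 22 higher and 0 lower, with C8b at 0.72 ± 0.13. Cidec, a lipid droplet protein, fell from a mean of 39.4 to 10.6 CPM (-1.90 ± 0.25), within a list of 28 genes of which 4 were lower and 1 higher; adjusted over the list alone, 1 was higher and 5 lower. Of 21 lipogenesis genes, 0 were higher and 4 lower (Pgd -0.54 ± 0.098, Me1 -0.44 ± 0.083); adjusted over the list alone, 0 were higher and 10 lower. The oxidation list had 1 of 46 higher (Eci2 0.41 ± 0.085) and 1 lower (Ucp2 -0.98 ± 0.21); adjusted over the list alone, 1 was higher and 1 lower. The cholesterol-synthesis list had 2 of 25 higher, Tm7sf2 (0.61 ± 0.17) and Insig1 (0.51 ± 0.15); adjusted over the list alone, 0 were higher and 0 lower. The median of the oxidation list was 0.094 on the TMM scale and -0.056 by library size. Under an estimated correlation the adjusted p of these lists was 0.478 to 0.796.

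In all, 1978 of 15597 genes passed, 1036 higher and 942 lower; at an absolute log2 fold change of at least 1, 62 were higher and 215 lower. Scaling by library size alone gave 406 higher and 2393 lower, with the median of all genes at -0.17 on the log2 scale; 3 of 21 lists past camera lost the call by library-size scaling, the immediate-early list among them (adjusted p = 0.134 to 0.213). DESeq2 called 3028 genes, and edgeR 1225 with a replicate block and 542 with all 22 libraries in one fit. The count depended on single libraries: it was 483 without vehicle 1, 903 without vehicle 2, 656 without vehicle 4, 957 without DTMB 2, 797 without DTMB 3 and 537 without DTMB 4, by group and replicate number. Without the libraries with acinar transcripts (2 vehicle and 3 DTMB libraries left) edgeR called 0 genes, with 2182 at an unadjusted p under 0.05; the median absolute log2 fold change of the 1978 genes was then 0.387 with a median SE of 0.134, against 0.462 and 0.107 with all libraries.

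The third comparison asked how many genes changed by HFD moved back with DTMB. Of the 4332 diet genes, 697 (16.1%) passed in the opposite direction with DTMB and 159 in the same direction. 410 were higher on HFD and lower with DTMB, where independent lists would share 143, and 287 were lower on HFD and higher with DTMB, where independent lists would share 130.1. Genes of smallest p were Map3k5 (gene ID 26408, chromosome 10, 19934101 to 20142750), a stress-activated kinase (-1.01 ± 0.080 with HFD and 0.77 ± 0.075 with DTMB); Nnmt (-0.91 ± 0.091 and 0.76 ± 0.086); Anxa2 (gene ID 12306, chromosome 9, 69453683 to 69491792) (2.22 ± 0.21 and -1.54 ± 0.18); Wwtr1, which encodes the coactivator TAZ (0.74 ± 0.090 and -0.72 ± 0.083); Rapgef4 (-1.06 ± 0.10 and 0.73 ± 0.097); and Fam129b (1.48 ± 0.16 and -1.06 ± 0.14). The vehicle libraries enter both comparisons with opposite sign. Across genes, which are not independent replicates, the log2 fold changes correlated at r = -0.419, and 20 simulated sets with no effect gave a mean of -0.458 (-0.539 to -0.369). The covariance was -0.163, against a simulated mean of -0.0629, a difference of -0.0999. Genes were simulated independently of each other, so the spread of the simulated sets is too narrow to judge this difference. With different vehicle libraries in each comparison (6 splits into 2 sets of 2) the covariance was -0.157 to -0.0391, and 3 to 342 genes moved back (median 25.5). The count was 180 without vehicle 1, 345 without vehicle 2, 1126 without vehicle 3, 219 without vehicle 4, 336 without DTMB 2, 337 without DTMB 3 and 223 without DTMB 4, and 0 without the libraries with acinar transcripts. It was 1125 by DESeq2, 1091 by library size alone and 389 with a replicate block.

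**Figure D3:**
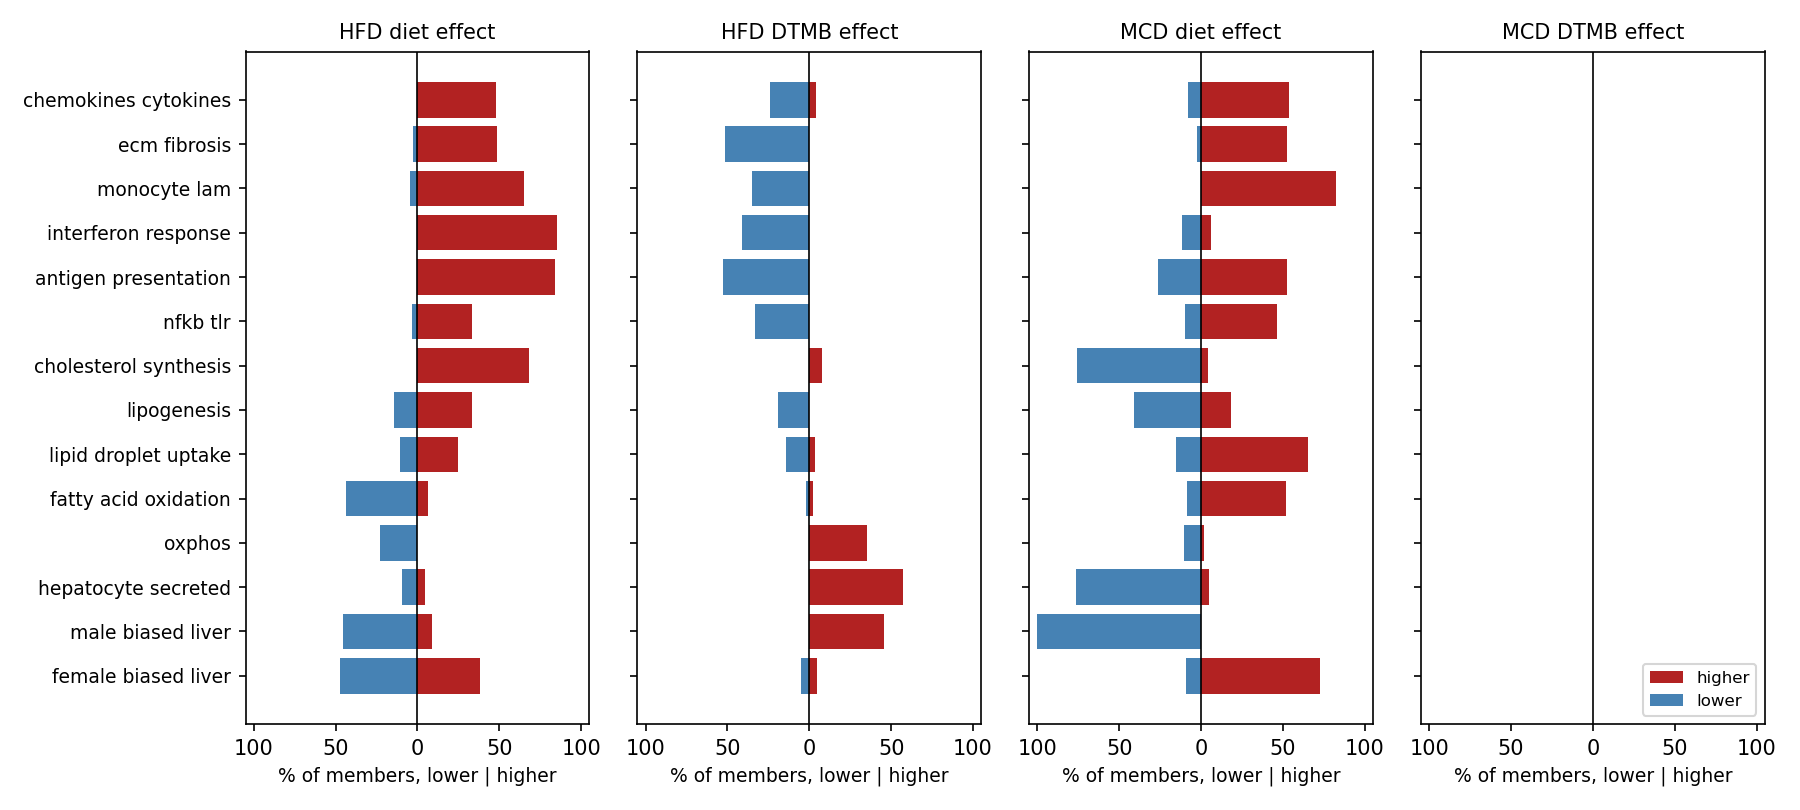
Share of each list's tested members past the threshold (x axis, percent of members; higher to the right, lower to the left) for 14 gene lists in the 4 comparisons. In the HFD cohort, 20 of 39 matrix genes were lower with DTMB, and in the MCD cohort all 22 male-biased genes were lower on the diet, while no list member passed with DTMB.

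The fourth comparison set MCD vehicle livers against normal-diet livers of the MCD cohort. On MCD, 22 of 22 male-biased genes were lower and 16 of 22 female-biased genes (2 lower) higher, lists that held with an estimated correlation (adjusted p = 0.0378 and 0.0429). 16 of 21 secreted hepatocyte proteins (1 higher) were lower. 19 of 23 monocyte and lipid-associated macrophage markers, 7 of 18 Kupffer and pan-macrophage markers, 17 of 26 lipid droplet and uptake genes (4 lower) and 20 of 38 matrix genes (1 lower) were higher, and these and the secreted list did not hold (adjusted p = 0.253 to 0.786 with an estimated correlation). By fry these lists passed (adjusted p = 1.96e-04 to 0.0451) except the Kupffer list (0.0808). The largest rises were Vmn2r3 (gene ID 637004, chromosome 3, 64258961 to 64287426), annotated as a vomeronasal receptor, with 44.0 ± 17.3 CPM (SD, n = 4) and no count on normal diet, at least 2882-fold higher; Sult1e1 (gene ID 20860, chromosome 5, 87575968 to 87591611), the estrogen sulfotransferase, 12.57 ± 0.57 on the log2 scale; and Sult2a3 (gene ID 629203, chromosome 7, 14067555 to 14123048), at least 729.9-fold higher. The largest falls were Mup5 (gene ID 17844, chromosome 4, 61831319 to 61858043), a major urinary protein, at least 3194-fold lower; Hsd3b5, -10.39 ± 0.71; and Trhde (gene ID 237553, chromosome 10, 114398820 to 114802302), at least 214-fold lower. Adjusted p lay between 1.54e-07 and 9.74e-04.

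All 22 of 22 male-biased genes fell. Mup3 was 122 ± 23.3 CPM (SD, n = 4) against 9205 ± 2059 CPM (SD, n = 4), -6.24 ± 0.29 on the log2 scale, the complement gene C6 fell (-3.80 ± 0.19), as did Selenbp2 (-5.12 ± 0.31). Female-biased genes had 16 of 22 higher and 2 lower, with Cyp2a4 at 6.16 ± 0.38, Cyp2b9 at 9.24 ± 0.64 and Fmo2 at 3.16 ± 0.22. No list other than these 2 held with an estimated correlation. Secreted hepatocyte proteins had 16 of 21 lower and 1 higher, with Serpina1c at -2.22 ± 0.18, Fetub at -1.38 ± 0.12 and Serpina1a at -1.86 ± 0.17 (adjusted p = 0.526 with an estimated correlation).

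Monocyte and lipid-associated macrophage markers had 19 of 23 higher and 0 lower. Gpnmb (gene ID 93695, chromosome 6, 49036518 to 49058182), a marker of lipid-laden macrophages, was 206 ± 97.3 CPM (SD, n = 4) against 0.302 ± 0.387 CPM (SD, n = 4), 9.36 ± 0.83 on the log2 scale, with Atp6v0d2 at 3.32 ± 0.30 and Trem2 at 5.51 ± 0.53. Kupffer and pan-macrophage markers had 7 of 18 higher and 0 lower, with Cd68 at 2.52 ± 0.41. Of 26 chemokines and cytokines, 14 were higher and 2 lower, with Tgfb1 at 1.27 ± 0.18 and Il1rn at 3.62 ± 0.52; adjusted over the list alone, 17 were higher and 2 lower. Of 38 matrix genes, 20 were higher and 1 lower, with the macrophage elastase Mmp12 at 7.71 ± 0.84; adjusted over the list alone, 20 were higher and 1 lower. Stellate markers had 9 of 16 higher and 0 lower, with Pdgfra at 1.95 ± 0.20. Immediate-early genes had 8 of 17 higher and 0 lower (Atf3 4.39 ± 0.37), mitochondrially encoded genes 11 of 13 lower and 0 higher (ND4L -0.87 ± 0.12), and erythroid genes 6 of 7 lower and 0 higher (Alas2, of heme synthesis, -2.28 ± 0.12), with camera adjusted p of 0.00366, 1.83e-04 and 0.00112. For the cell and matrix lists camera adjusted p ran from 1.71e-13 for the monocyte list to 0.0114 for the Kupffer list. The adjusted p with an estimated correlation of the lists in this paragraph was 0.526 to 0.786.

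Of 25 cholesterol-synthesis genes, 1 was higher and 19 lower, with Tm7sf2 at -2.86 ± 0.18, Sc5d at -1.23 ± 0.12 and Ebp at -1.33 ± 0.15; adjusted over the list alone, 1 was higher and 21 lower. Of 46 oxidation genes, 24 were higher and 4 lower, with Cyp4a31 at 4.23 ± 0.31, the hormone Fgf21 at 6.50 ± 0.51 and Acot4 at 2.47 ± 0.21; adjusted over the list alone, 24 were higher and 5 lower. Of 26 lipid droplet and uptake genes, 17 were higher and 4 lower, with the fatty acid transporter Cd36 at 473 ± 58.9 CPM (SD, n = 4) against 39.6 ± 1.87 CPM (SD, n = 4), 3.58 ± 0.13 on the log2 scale, and Lipc at -2.10 ± 0.17; adjusted over the list alone, 17 were higher and 5 lower. Of 22 lipogenesis genes, 4 were higher and 9 lower. Scd1, the stearoyl-CoA desaturase, fell to 115 ± 45.7 CPM (SD, n = 4) against 9936 ± 2843 CPM (SD, n = 4), -6.44 ± 0.65 on the log2 scale, while Fads2 rose by 1.52 ± 0.12; adjusted over the list alone, 5 were higher and 9 lower. With an estimated correlation the adjusted p of these lists was 0.253 to 0.786. The median of the lipogenesis list was -0.37 on the TMM scale and 0.093 by library size.

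In all, 6626 of 16037 genes passed, 3253 higher and 3373 lower, of which 1910 and 1144 had an absolute log2 fold change of at least 1. Scaling by library size alone gave 7683 higher and 1170 lower, with the median of all genes at 0.47 on the log2 scale. 7 of 20 lists past camera lost the call by library-size scaling, among them the Kupffer, chemokine and immediate-early lists (adjusted p = 0.0748 to 0.551). Without normal-diet replicate 4, which held acinar transcripts, 5739 genes passed; with it, 6 of 8 acinar genes were lower, such as Pnlip (-8.30 ± 2.55).

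The fifth comparison set MCD livers of mice given DTMB (n = 3) against MCD vehicle livers (n = 4). 1 of 16037 genes passed in edgeR's test, LOC108168464, a locus of low expression named here after its value was seen, with 0.592 ± 0.225 CPM (SD, n = 3) against 0.0406 ± 0.0138 CPM (SD, n = 4), 3.79 ± 0.46 on the log2 scale, adjusted p = 0.0369. It did not pass without any 1 of the 11 libraries of the cohort. 857 of 16037 genes had an unadjusted p under 0.05, close to the share of 0.05 that no effect would give. DESeq2 called 13 and limma-voom 0. No member of any list passed over all genes. In the matrix list (38 genes) the log2 fold changes of smallest p were Timp2 -0.89 ± 0.24, Tgfb1 -0.53 ± 0.19 and Col4a2 -0.57 ± 0.21, and Col1a1 was -1.06 ± 0.66. In the monocyte list (23 genes) they were Spp1 -1.13 ± 0.35, Fabp5 -1.06 ± 0.39 and Gpnmb -1.62 ± 0.61. Oxidation genes were at 0.57 ± 0.21 (Acot4), 0.34 ± 0.14 (Decr2) and 0.79 ± 0.37 (Fgf21), respiratory chain subunits at 0.29 ± 0.17 (Ndufb8), 0.16 ± 0.11 (Ndufs4) and 0.23 ± 0.17 (Ndufa5), and CAR and PXR targets at 0.47 ± 0.19 (Nr1i2), 0.45 ± 0.19 (Cyp3a25) and 0.57 ± 0.26 (Ugt1a9). Endothelial markers were at -0.57 ± 0.17 (Stab1), -0.36 ± 0.12 (Oit3) and -0.33 ± 0.14 (Pecam1), and the stellate marker Pdgfrb at -0.79 ± 0.29. Among lipid genes G0s2, an inhibitor of lipolysis, was at 1.28 ± 0.26, Fabp4 at -0.89 ± 0.24, Fads2 at 0.45 ± 0.13, Fads1 at 0.40 ± 0.15, Sc5d at 0.35 ± 0.13 and Msmo1 at 0.41 ± 0.27; the chemokine Cxcl11 was at 0.88 ± 0.42. Adjusted p of these genes lay between 0.919 and 0.924. 19 of 41 lists passed camera at the preset correlation, with the matrix list at a median of -0.65 and adjusted p = 2.08e-11. Among them were cholangiocyte markers (median -0.827, adjusted p = 7.51e-04) and erythroid genes (-0.582, 0.00222). Of the lists that track RNA quality and handling, immediate-early genes were at -0.439 (1.26e-04) and mitochondrially encoded genes at 0.181 (4.07e-04). With an estimated correlation none passed (adjusted p = 0.534 for the matrix list), and none did by fry; 3 of 19 lists past camera lost the call by library-size scaling (adjusted p = 0.0514 to 0.116). Adjusted over the list alone, 3 lipid droplet genes were higher and 1 lower, and no gene passed in the other 5 study themes. No gene changed by MCD passed in the opposite direction with DTMB (7 did by DESeq2). Across genes the covariance was -0.152, against -0.0606 in simulated sets, which lack correlation between genes, and -0.162 to 0.0670 with split vehicle libraries.

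**Figure D4:**
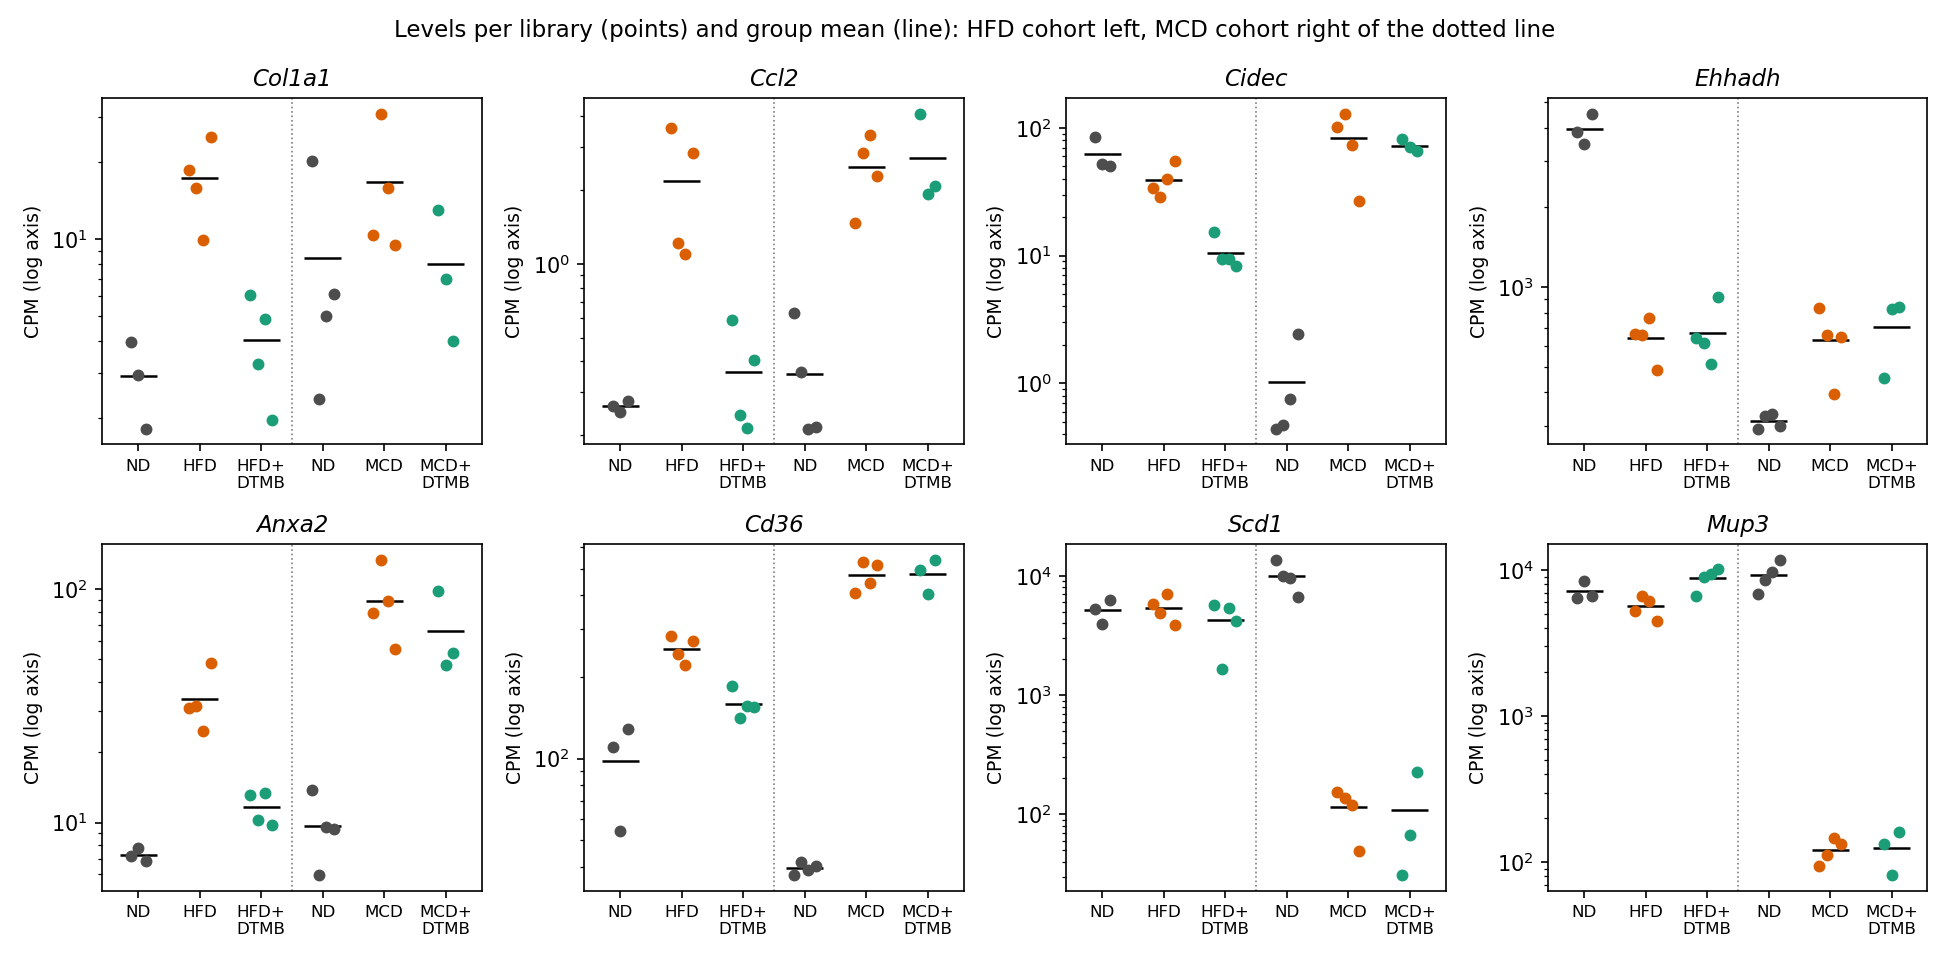
CPM of 8 genes (y axes, log scale) in every library (points) with the group mean (lines), in the HFD cohort (left of the dotted line) and the MCD cohort (right); each cohort was scaled on its own. Col1a1, Ccl2, Cidec and Anxa2 are lower with DTMB than in HFD vehicle livers, and Scd1 and Mup3 are lower, and Cd36 higher, in both MCD groups than on normal diet.

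The last comparisons tested differences between the cohorts in one fit of all libraries. The diet effect differed at 5847 of 16541 genes; the diets, and the normal-diet groups, differ between cohorts, so diet and cohort cannot be told apart there. Zcchc24 was 0.31 ± 0.082 on HFD and -2.96 ± 0.14 on MCD, Tlcd2 1.62 ± 0.14 and -3.73 ± 0.22, Lrit1 0.22 ± 0.13 and -6.43 ± 0.37, Alas2, of heme synthesis, 0.42 ± 0.092 and -2.28 ± 0.12, Mup3 -0.34 ± 0.17 and -6.24 ± 0.29, and Adh7 -1.76 ± 0.16 and 2.19 ± 0.17. The adjusted p of these differences lay between 1.20e-10 and 6.52e-10. Of genes called in both diets, 556 were higher in both (455 for independent lists), 407 lower in both (426), 723 higher on HFD and lower on MCD (513) and 393 the reverse (377). Without the libraries with acinar transcripts 2285 genes differed.

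The DTMB effect differed between cohorts at 0 genes in edgeR's test, with 1415 at an unadjusted p under 0.05; DESeq2 called 38 and limma-voom 11. By edgeR's test 1978 calls in one cohort and 1 in the other thus do not show that the effects differ. The genes of smallest p were Limk1 (-1.38 ± 0.19 with HFD and 0.10 ± 0.18 with MCD), Zkscan14 (0.56 ± 0.13 and -0.48 ± 0.16), Efna1 (0.55 ± 0.17 and -1.21 ± 0.28), Impdh2 (0.24 ± 0.074 and -0.30 ± 0.092), Siae (-0.45 ± 0.076 and 0.21 ± 0.10) and Sytl4 (-0.92 ± 0.20 and 0.44 ± 0.18), with adjusted p of the difference between 0.137 and 0.150. All 6 passed by DESeq2 (adjusted p = 0.00138 to 0.00436) and 2, Zkscan14 and Siae, by limma-voom; over all alternatives the adjusted p of the 6 ran from 0.00138 to 1. No gene was called in both DTMB comparisons. Across 15263 genes the DTMB changes of the cohorts, which share no library, correlated at r = 0.270 (Spearman 0.350). Of 1966 genes called with DTMB on HFD, 75.0% had the same sign with DTMB on MCD. In the MCD cohort Ccl2 was at 0.12 ± 0.39, Cidec at -0.20 ± 0.51, Hsd3b5 at -0.05 ± 1.05, Map3k5 at 0.07 ± 0.17 and Anxa2 at -0.43 ± 0.33, none past the threshold.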

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

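The tests of equal effect size, of non-hepatocyte markers, of scaling and of a general hepatocyte fall were chosen only after the results were seen; the test of library subsets was set after the count without acinar libraries was known, and before any other subset was fitted. Single values that stood apart were sought among the genes named and the acinar sum in groups of 4 libraries, by the gap to the nearest library over the group's range. 37 of 362 group tests (10.2%) stood apart, where chance alone gives about 1 in 20. In HFD vehicle replicate 1 these were Efna1 at 22.6 CPM (others 18.9 to 19.0), Rapgef4 at 72.0 CPM (others 85.6 to 86.7), Tap1 at 43.6 CPM (others 28.1 to 29.8), Tap2 at 26.8 CPM (others 21.4 to 22.1), Tlr5 at 13.4 CPM (others 16.4 to 16.9). In HFD vehicle replicate 3 these were Insig1 at 130.3 CPM (others 89.3 to 95.8), Mcm4 at 3.52 CPM (others 5.16 to 5.28), Msmo1 at 123 CPM (others 70.7 to 76.6), Mvd at 8.96 CPM (others 4.999 to 5.60). In HFD vehicle replicate 4 they were the acinar sum at 3409 CPM (others 0.1002 to 487), Amy2a5 at 338 CPM (others 0 to 57.5), Ier2 at 10.96 CPM (others 7.63 to 7.92), Siae at 66.6 CPM (others 61.1 to 61.8), Try5 at 88.3 CPM (others 0 to 14.3). For HFD DTMB replicate 1 the value was Cidec at 15.3 CPM (others 8.24 to 9.38), for replicate 4 Ndufa2 at 53.2 CPM (others 47.9 to 48.8), and for replicate 3 the values were the acinar sum at 1794 CPM (others 0.0722 to 1.24), Amy2a5 at 353 CPM (others 0 to 0.186), Try5 at 39.8 CPM (others 0 to 0.0508), Wwtr1 at 22.3 CPM (others 18.9 to 19.3). On normal diet in the MCD cohort, replicate 1 had Cyp2a4 at 30.4 CPM (others 12.03 to 15.0), Fads1 at 731 CPM (others 522 to 530.5), Lipc at 134 CPM (others 179 to 188), Mmp12 at 1.42 CPM (others 0.108 to 0.158). Replicate 2 there had Cd68 at 9.93 CPM (others 3.35 to 4.31), Timp2 at 6.38 CPM (others 10.9 to 11.7), and replicate 4 the acinar sum at 374 CPM (others 0.413 to 3.85), Cidec at 2.44 CPM (others 0.444 to 0.755), Ctrb1 at 51.4 CPM (others 0 to 0.329), Pnlip at 57.8 CPM (others 0 to 0.639). Among MCD vehicle libraries, replicate 1 had the acinar sum at 12.9 CPM (others 0.642 to 0.966), Ctrb1 at 2.81 CPM (others 0 to 0.0468), Pnlip at 0.170 CPM (others 0 to 0). Replicate 2 of that group had Fabp5 at 39.4 CPM (others 20.6 to 23.8), Pdgfrb at 17.5 CPM (others 11.3 to 11.6), Trem2 at 18.5 CPM (others 8.18 to 9.95), and replicate 4 Zkscan14 at 2.70 CPM (others 3.48 to 3.63).

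Other splits of the same libraries were refitted. For the HFD diet 1 of 35 splits, the real one, gave as many genes (4332, highest other 1327), for HFD DTMB 1 of 35 (1978, highest other 0) and for the MCD diet 1 of 35 (6626, highest other 5). These counts were above those of every other split. As 1 of 35 is the smallest share these splits can give, and several counts were tested, chance is not excluded. The MCD DTMB count was within the range of other splits, as 4 of 35 splits gave 1 gene or more (highest other 1). So was the number of lists past camera at the preset correlation: 14, 12, 12 and 16 of 35 splits gave as many in the HFD diet, HFD DTMB, MCD diet and MCD DTMB comparisons, with real counts of 19, 21, 20 and 19 and highest others of 29, 28, 25 and 26. A small camera p at the preset correlation does not exclude chance in these libraries. For HFD reversal 1 of 35 splits gave as many genes (697, highest other 0). No other split called a DTMB gene there, so this only repeats the test of the DTMB count and tells nothing separate about reversal. For MCD reversal, with 0 genes, 35 of 35 did, which a count of 0 fixes in advance. The difference of diets had 1 of 100 splits with as many genes (5847, highest other 4305). The difference of DTMB effects, with 0 genes, had 100 of 100, again fixed in advance and telling nothing about chance. 8 other splits of the latter called any gene. The highest called 2033, far above the real count, which a structure of the samples could give, but this was not tested. Splits were drawn in each cohort on its own. In either difference a split could thus keep the real groups of 1 cohort and change those of the other.

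Many genes were called with DTMB in the HFD cohort and 1 in the MCD cohort. Fewer DTMB libraries could contribute: without 1 DTMB library the HFD count was as low as 537, still far above 1. Effects of equal size cannot be told apart from smaller ones in the MCD cohort, as the noise-corrected slope of MCD on HFD changes was 0.426 ± 0.311 (jackknife SE, 11828 genes). The test set beforehand cannot separate acinar RNA from the loss of libraries. 39 of 72 subsets with the same group sizes, each with 1 normal-diet library, gave as few calls as the subset without acinar libraries. That subset gave none, which cannot be undercut, so the bound was wrong. At these same sizes, subsets with vehicle replicates 1 and 4, which held acinar transcripts, all gave many calls. Those with vehicle replicate 3 (acinar sum 0.162 CPM) gave few or none, whatever the other vehicle library. Vehicle replicate 2 with 1 or 4 gave many only where DTMB replicate 1 (0.0722 CPM) was left out. With all other libraries kept, the count was 2562 without vehicle 3 and 2482 without DTMB 1. Group size alone thus does not set the count, and neither does acinar RNA alone. Other traits of single libraries were not separated from acinar RNA. A weaker response to DTMB on MCD remains an open biological explanation, and the difference itself passed at 0 genes in edgeR's test (1415 at an unadjusted p under 0.05, 38 by DESeq2, 11 by limma-voom).

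With DTMB on HFD, 20 of 39 matrix genes, 10 of 30 NF-kB and Toll-like receptor genes, 6 of 25 chemokines and cytokines (1 higher) and 8 of 23 monocyte and lipid-associated macrophage markers were lower. Of 18 Kupffer markers 1 was, near the share over all genes (942 of 15597). No list held with an estimated correlation (adjusted p = 0.478 to 0.546). By fry the matrix, NF-kB and monocyte lists passed (adjusted p = 0.0337 to 0.0405). The chemokine and Kupffer lists did not (fry adjusted p = 0.0501 and 0.181). A smaller share of all non-hepatocyte cells alike cannot be told apart from changes in single cell types: mean log2 CPM differed by -0.987 for monocyte and lipid-associated macrophage, -0.590 for Kupffer, -0.279 for endothelial, -0.195 for cholangiocyte and -0.182 for stellate markers (exact permutation p = 0.0571 to 0.171) and by 0.267 for secreted hepatocyte proteins (exact permutation p = 0.0286, the smallest that 70 permutations can give), and the range of 0.805 over the 5 non-hepatocyte lists had an exact permutation p of 0.0571. The medians of the matrix and monocyte lists were -0.792 or lower under TMM, RLE and library-size scaling. This cannot decide on scaling as a cause. RLE gave nearly the same median of all genes as TMM (-0.0146 and -0.0149), and library size a lower one (-0.166), which could only deepen the falls. Without the acinar libraries edgeR called 0 genes (2182 at an unadjusted p under 0.05), and the matrix median was -0.560, against -0.792 with all, with a mean difference of -0.651 ± 0.242 (SE, 3 and 2 libraries), too few to decide. Medians were also lower for B and plasma cell markers (-1.02, 1 of 16 past the threshold), neutrophil markers (-0.611, 0 of 7) and T and NK cell markers (-0.582, 0 of 17). These lists were not in the range test. B and plasma cell markers passed camera at the preset correlation (adjusted p = 0.0210), while neutrophil and T and NK cell markers did not (0.146 and 0.0507). None of the 3 passed by fry (adjusted p = 0.200 to 0.212). Whether the fall was particular to macrophage and matrix genes was thus not settled. Fewer macrophages, or lower expression within them, may contribute, which bulk RNA cannot separate.

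Male-biased genes were lower and female-biased genes higher on MCD. Female mice are argued against: Xist was at most 0.0940 CPM in the MCD cohort, and the sum of Y-linked genes was at least 85.8 CPM. A general fall of hepatocyte transcripts alone would not raise female-biased genes, whose median log2 fold change was 3.73 (1 of 35 splits as high, highest other 1.51). That rise is part of the pattern itself, so it cannot tell whether a general fall added to the fall of male-biased genes. Secreted hepatocyte proteins were also lower (16 of 21, 1 higher), with a median of -0.827 against -5.11 for male-biased genes. A loss of the male pattern of hormone signals to the liver on MCD is a hypothesis found in these data, and no hormone was measured. Reads shared between Mup, Cyp2a, Cyp2b and Sult2a copies were not tested.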

How the results depend on the processing

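Scaling by library size alone and leaving out libraries with acinar RNA were chosen after seeing the data; the other settings were planned. Counts are of genes past the threshold unless lists are named. DESeq2 gave 3028 for HFD DTMB, 13 for MCD DTMB, 38 for the difference of DTMB effects, 1125 and 7 for HFD and MCD reversal and 3 genes shared between the DTMB comparisons; limma-voom gave 11 for the difference. For MCD DTMB limma-voom, no filter, the stricter filter, the block, the 2 groups alone, all libraries in one fit and leaving out acinar libraries each gave 0. Without acinar libraries the counts were 655 for the HFD diet (median 906.5 in subsets of the same sizes), 0 for HFD DTMB, 0 for HFD reversal and 2285 for the difference of diets. At an absolute log2 fold change of at least 1 they were 1139, 277 and 3054 for the HFD diet, HFD DTMB and the MCD diet. All libraries in one fit gave 542 for HFD DTMB. The replicate block gave 1225 for HFD DTMB and 389 for HFD reversal. A pairing by number was not shown and is not excluded: 5 of 10 pairs of the same number correlated above 0.1 in the HFD cohort and 0 of 10 in the MCD cohort. HFD reversal was 1091 by library size and 25.5 (median) with split vehicle libraries. Lists past the threshold with an estimated correlation numbered 0 for the HFD diet, 0 for HFD DTMB, 2 for the MCD diet and 0 for MCD DTMB. By fry they numbered 20 for the HFD diet, 9 for HFD DTMB, 19 for the MCD diet and 0 for MCD DTMB. Leaving out 1 library gave 3090 to 4401 genes for the HFD diet, 483 to 2562 for HFD DTMB, 5600 to 6550 for the MCD diet, 0 to 0 for MCD DTMB, 4865 to 5885 and 0 to 2 for the differences of diet and DTMB effects, and 180 to 1126 for HFD reversal. The difference of DTMB effects had 1 gene without HFD DTMB replicate 2, 2 without MCD vehicle replicate 2 and 1 without MCD DTMB replicate 3.

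The sign of a log2 fold change turned for 6 genes, none past the threshold in that comparison. Leaving out 1 library, Try5 ranged from -10.3 to 1.07 with HFD DTMB, and with MCD DTMB Limk1 from -0.0229 to 0.200, Ccl2 from -0.309 to 0.314, Cidec from -0.514 to 0.0990 and Hsd3b5 from -0.543 to 0.472. In the MCD DTMB comparison limma-voom gave -0.0231 for Limk1 and -0.248 for Ccl2, the block -0.102 for Ccl2 and 0.343 for Hsd3b5, and library size alone -0.0135 for Limk1 and -0.0290 for Map3k5. Of the values of named genes under other settings, 210 lost the threshold and 12 gained it for HFD DTMB, 27 and 1 for the HFD diet, 7 and 0 for the MCD diet, 17 and 2 for MCD DTMB, and 0 and 8 for the difference of DTMB effects (6 by DESeq2, 2 by limma-voom).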

Other observations

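The test of HFD gene sets in the MCD cohort was chosen only after the sharing between cohorts was seen, and the lists described here were picked after their results were seen. On HFD, of 18 periportal genes 10 were lower and 3 higher, with Sdsl, of serine and threonine breakdown, at -2.35 ± 0.10. Of 18 pericentral genes 8 were higher and 1 lower, with Lect2 at 1.82 ± 0.10 (adjusted p = 0.637 for both lists with an estimated correlation). Acute-phase genes had 12 of 29 higher and 1 lower (Serpina3n 1.12 ± 0.11), and female-biased genes 8 of 21 higher and 10 lower. In the list of ER stress and amino acid response genes 15 of 27 were higher and 3 lower, and in the methionine and one-carbon list 5 of 33 higher (Gamt 1.43 ± 0.14) and 10 lower. With DTMB on HFD, proliferation genes had 8 of 37 lower and 1 higher (Mcm4 -0.81 ± 0.15), the ER stress list 12 of 27 higher and 0 lower (Xbp1 0.51 ± 0.087), and clock genes 5 of 18 higher and 1 lower (Tef 0.68 ± 0.13). Under an estimated correlation the adjusted p of these lists was 0.637 to 0.638 for the diet and 0.478 for DTMB.

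On MCD, neutrophil markers had 6 of 9 higher and 0 lower (S100a8 2.95 ± 0.61). Bile acid and sterol genes had 14 of 28 lower and 5 higher (Slc27a5 -1.88 ± 0.15), with a median of -0.30 on the TMM scale and 0.16 by library size. Lists with members moving both ways were acute phase (7 of 29 higher and 7 lower, Lcn2 5.92 ± 0.63), ER stress (8 of 27 and 13) and methionine and one-carbon (7 of 33 and 8), the last with Psat1, of serine synthesis, at 5.21 ± 0.34. The adjusted p with an estimated correlation of these lists was 0.540 to 0.960.

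The hypothesis that DTMB moved the MCD livers along the directions it had on HFD was tested with the sets of genes called with DTMB on HFD. The mean log2 fold change with DTMB on MCD was 0.111 for 1034 genes higher with DTMB on HFD. It was -0.165 for 932 genes lower with DTMB on HFD. The difference of 0.276 was reached by 7 of 35 splits of the MCD libraries (highest other 0.500). The signs went along (80.7% and 68.7% the same), but a shift beyond that between other groupings of these libraries was not shown.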
